A study of Homo sapiens with 6 samples.

How the data were processed

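Total RNA of U87 cells transfected with siRNA a or siRNA b against RVT1 was hybridized with RNA of cells given a control siRNA to 2-colour Agilent arrays. Per the labels, the knockdown RNA carried Cy5 and the control RNA Cy3 on every array, and each array is 1 of 3 biological replicates of its siRNA. The groups were taken from the labels: 3 arrays of siRNA a against Control siRNA_1 and 3 of siRNA b against Control siRNA_2.

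The deposited scanner files came from Agilent Feature Extraction 10.7.3.1, named in the file headers and in the submitters' processing notes, which also name limma without a version. Per the file headers, the mean signal, the local background and the processed signal of each channel are intensity values on a linear scale, and the processed signals are background-subtracted, spatially detrended and dye-normalized. Per the file headers, LogRatio is the log10 of red over green processed signal. The authors' series table holds log10 ratios equal to 0.999 times LogRatio in feature order, with its probe names displaced by 1 line; 180879 names match the feature 1 line below and 2185 that on the same line. The median of each of its 6 columns was 0.0, 0.0, 0.0, 0.0, 0.0 and 0.0. In 262 cells the table departed from that factor by more than 0.0001, and 41 cells were missing. LogRatio departed from the processed signals by more than 0.01 at 1778 spots of siRNA b replicate 1 and siRNA a replicate 2, so the mean signals were used. On siRNA b replicate 1 the red background-subtracted signal departed from mean minus background by more than 0.3 on the log2 scale at 88134 of the spots well above background. The counts of spots well above background in the file headers differed from those in the data on all 6 arrays, with 109947 to 131840 in green against 96726 to 130964; the values of the data were used and the cause was not tested. The header of siRNA b replicate 2 names another slide and a scan 4 years before those of the other arrays, and a 2-colour protocol where the other 5 headers name a 1-colour one. The 2-colour protocol is named instead in the name of the file of siRNA b replicate 3, so the slide and the replicate number of these 2 arrays are less certain than those of the others. All files hold both channels.

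Each array held 180880 features, of which 4974 (2.75%) were controls. The 71816 probes had 2 to 5 spots each and 69395 distinct sequences. No spot was saturated. Background was corrected with normexp (offset 50) on the mean signal and the median local background. Log2 ratios of red over green were normalized by loess within arrays, with controls and spots the scanner software marked as outliers at weight 0, and the spots of a probe were averaged. A probe was tested when it lay well above background in at least 1 channel on at least 3 of the 6 arrays, which 56464 probes (78.6%) did; 1 of them had no value for siRNA b. The 1559 pairs of probes of the same sequence had log2 ratios that correlated at 0.879 to 0.951 within an array, which gives an SD per probe of 0.0717 to 0.0877, against an SD over all probes of 0.261 to 0.425.

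The model was fitted with limma 3.58.1 in R 4.3.3 over all 6 arrays with 1 mean per siRNA, and Python 3.11.15 was used to read the files. The comparisons were siRNA a against its control, siRNA b against its control, the mean of both, and siRNA a minus siRNA b, each with moderated two-sided tests and Benjamini-Hochberg adjustment at 0.05. On simulated data of this size with 200 changed probes, the comparison of siRNA a with its control recovered 72% of 2-fold and 98% of 4-fold changes with 4.37% of its calls wrong, and that of siRNA a with siRNA b recovered 38% and 92% with 5.11% wrong. The changed probes were drawn from those with a background-subtracted green signal above 200, and the arrays were simulated without pairs. The tRNA probes were simulated lower on all arrays as well, and their calls against the control were not counted as wrong. The spread between arrays was assumed and not taken from these arrays. The rates thus hold for bright probes, unpaired arrays and that assumed spread.

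The labels and file names give the replicate number and the slide. After the group means were removed, arrays of the same replicate number correlated at 0.232, 0.532 and 0.403 across probes. Those of different numbers correlated at -0.36 to 0.02, so the labelled numbers were kept as pairs. With replicates 2 and 3 of siRNA b exchanged the correlations were -0.31 and -0.36. Deviations from a mean of 3 arrays sum to 0, so positive values at the same number push the others below 0. The exchanged values are therefore not separate evidence. Values with the replicate number as a block are given beside the main ones. In comparisons with a control, this block takes the spread between replicate numbers out of the error. Its counts there can run too high and its p too low, and it suits only siRNA a minus siRNA b. Slide 1 held replicates 1 and 2 of both siRNAs and slide 2 replicate 3.

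The comparisons, tests, thresholds, gene lists and a rule for named genes were set before the data were examined. The gene lists, the probes of RVT1 and of PVT1, and gene symbols were not used, because none of the 71816 probe identifiers occurs in the gene table at hand and the files hold no other names. In place of the gene lists, probe classes were read from the identifiers after the data were seen. The 16 numbered RNAs and the 4 vault RNAs were separated from a joint class of 22 small RNA probes after their ratios had been seen. The joint class holds both groups, 1 ribozyme probe and 1 probe for the RNA of the signal recognition particle. It was therefore tested as well, among 9 classes, and rests mostly on the same 16 probes. Of the numbered RNAs, 9 share 20 bases with another of them. Classes of at least 4 probes, 10 in each comparison, were tested with camera on the moderated statistics (two-sided, preset correlation 0.01, Benjamini-Hochberg over classes), with camera at an estimated correlation and with fry. The last 2 used probes with a value on all 6 arrays, which 14 of the 16 numbered RNAs, 7 of the 10 rRNA probes and all 85 tRNA probes had.

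The rule for named genes was shortened to probes of the last 2 comparisons. For the mean of both siRNAs these were the 2 highest and the 2 lowest log2 ratios among probes that passed with the same sign on all 6 arrays. For siRNA a against siRNA b, where none passed, they were the first 2 of each direction among the 10 smallest p without overlap between the groups.

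The alternatives were the processed signals, no background subtraction, median centring without loess, scaling between arrays, no filter and a stricter one (39002 probes), marked spots kept, slide or replicate blocks, an intensity trend, the authors' table, only the 3 arrays of an siRNA, a fold of at least 2, and leaving out each array. Added after the data were seen were the slide from the file headers as a block, removal of a GC trend per array, slide 1 alone, pairs of arrays with different replicate numbers, the joint class of small RNAs and its sets matched on brightness, all alternatives for probe classes and named probes, and the correlation on each slide and without each array.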

Results

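RNA was measured in U87, a human glioblastoma cell line, after transfection with small interfering RNAs (siRNAs), short double-stranded RNAs that lead to the breakdown of a matching transcript. The target was a long noncoding RNA that the labels call RVT1. The sample labels name siRNAs, which is followed here, while the series description names sh- constructs. Each of the 6 Agilent arrays compared RNA from 1 knockdown, in the red Cy5 channel, with RNA from cells given a control siRNA, in the green Cy3 channel. There were 3 arrays for siRNA a, against Control siRNA_1, and 3 for siRNA b, against Control siRNA_2. Every array held 175906 spots that were not controls, which carried 71816 probes of 60 bases. The median brightness of these spots on the siRNA a arrays was 109, 173 and 115 in green and 164, 302 and 183 in red, for replicates 1, 2 and 3. On the siRNA b arrays it was 91.8, 170 and 129 in green and 195, 267 and 182 in red. Between 55.0% and 74.5% of the spots in green, and between 69.3% and 80.7% in red, lay well above background. The number of arrays, 3 per siRNA, limits the precision. Results are given per probe and per RNA class, because the files pair no probe with a gene. The files do hold the probe sequences, but these were not matched to genes, so the level of RVT1 itself was not read.

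The first comparison asked which RNAs differed between cells given siRNA a and cells given Control siRNA_1. Transfer RNAs (tRNAs), which carry amino acids to the ribosome, lay lower relative to the other RNAs: their 85 probes had a median log2 ratio of -0.37, and the array medians were -0.37 ± 0.11 (SD, n = 3), below 0 on all 3 arrays. A group of 16 probes whose identifiers give an RNA number but no class had a median log2 ratio of 0.75 and array medians of 0.71 ± 0.22 (SD, n = 3), with members from -0.17 (RNA143590) to 1.16 (RNA143595); the median was 1.34 with median centring and 0.45 with the authors' table. Of the tRNA probes, 30 passed the test as lower and none as higher; of the numbered RNAs, 6 passed as higher and none as lower. With the replicate number as a block these counts were 51 tRNA probes lower and 11 numbered RNAs higher. That block leaves the spread between replicate numbers out of the error, so such counts against a control can be too high. The 10 probes whose identifiers name ribosomal RNA (rRNA), the RNA of the ribosome itself, had a median log2 ratio of 0.13, and 1 of them passed as higher. Of the numbered RNAs, 13 have numbers within the range of the rRNA identifiers and may be rRNA, but were not counted there. Camera, which compares a class with all other probes, gave adjusted p = 1.42e-30 for tRNA and 0.0460 for rRNA at a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.114 and 0.878, so neither class call held. Fry, which tests whether the members of a class move 1 way on balance, gave adjusted p = 0.00434 for tRNA and 0.252 for rRNA. The numbered RNAs were separated from a joint class of 22 small RNA probes after their ratios had been seen, so the test is given for the joint class, whose median was 0.49: camera gave adjusted p = 1.13e-05, the estimated correlation adjusted p = 0.922 and fry 0.0995. When each array was centred on its median without loess, the median of the tRNA probes was -0.01 and that of all probes 0.12, against -0.37 and 0.01 with loess.

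Across all probes, 2034 of 56464 tested passed the test for siRNA a, 1319 higher and 715 lower than in the control. The large changes were nearly all increases: of the 59 probes that passed with at least a 4-fold change, 58 were higher and 1 was lower. The spread was estimated over all 6 arrays as if independent, although arrays of the same replicate number were correlated. With only the 3 arrays of siRNA a, 464 probes passed. With the replicate number as a block, which leaves out the spread between replicates, 6903 probes passed. The share of higher probes, 64.8%, became 87.0% of 10868 probes with median centring (9451 higher, 1417 lower) and 79.8% of 1773 with the scanner software's processed signals (1414 higher, 359 lower). It was 63.9% of 1777 with the authors' table and 58.5% of 3360 without siRNA b replicate 1. With the slide as a block 780 probes passed, with the slide named in the file headers as the block 4 passed, and 2 passed on slide 1 alone; slide 2 held 1 array per siRNA, too few for a test. Single arrays decided the count: it was 1283, 41 or 12 without siRNA a replicate 1, 2 or 3, and 3360, 939 or 627 without siRNA b replicate 1, 2 or 3.

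The second comparison asked the same of siRNA b against Control siRNA_2. The tRNA probes lay lower here too, with a median log2 ratio of -0.41 and array medians of -0.41 ± 0.07 (SD, n = 3), below 0 on all 3 arrays. The numbered RNAs had a median of 0.54 and array medians of 0.53 ± 0.40 (SD, n = 3), the lowest being 0.09 in replicate 1, with members from -0.23 (RNA143590) to 1.01 (RNA143592); the median was 1.26 with median centring and 0.39 with the authors' table. Of the tRNA probes 49 passed as lower and none as higher, and of the numbered RNAs 5 passed as higher and none as lower, or 55 and 10 with the replicate number as a block. Camera gave adjusted p = 5.67e-29 for tRNA and 0.0264 for the joint class of small RNAs, whose median was 0.30. With an estimated correlation the adjusted p was 0.131 and 0.717, so neither call held, and fry gave 0.00312 and 0.264. The rRNA probes, without the 13 numbered RNAs in the rRNA number range, had a median of 0.05 (adjusted p = 0.443 by camera). With median centring the median of the tRNA probes was -0.03 and that of all probes 0.14, against -0.41 and 0.02 with loess.

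Across all probes, 6817 of 56463 passed for siRNA b, 4223 higher and 2594 lower. Again the large changes were nearly all increases: 137 probes passed with at least a 4-fold change, of which 135 were higher and 2 lower. The spread was again estimated over all 6 arrays as if independent. With only the 3 arrays of siRNA b, 3702 probes passed. With the replicate number as a block, which leaves out the spread between replicates, 11906 probes passed. The share of higher probes, 61.9%, became 83.6% of 17399 probes with median centring (14545 higher, 2854 lower). With the processed signals it was 73.6% of 6697 (4929 higher, 1768 lower). It fell to 56.2% of 6654 with the authors' table (3739 higher, 2915 lower). Without siRNA b replicate 1 the share fell as well, with 2271 higher and 2013 lower among 4284 probes. With the slide as a block 4715 probes passed, with the header's slide as the block 3762 passed, and 2 passed on slide 1 alone. The count was 3939 without siRNA a replicate 3, and 4284, 1365 or 1196 without siRNA b replicate 1, 2 or 3.

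The third comparison asked which changes the siRNAs had in common, as the mean of both against the controls. It took the 6 arrays as independent. Arrays of the same replicate number were correlated, so its SEs and p can be too small and its counts too high. The probe A_24_P270460 was 29.0-fold higher after knockdown (log2 4.86, SE 0.07, adjusted p = 1.89e-06), at 4.85 ± 0.19 with siRNA a and 4.87 ± 0.18 with siRNA b (SD, n = 3 each). A_23_P64828 was 21.1-fold higher (log2 4.40, SE 0.21, adjusted p = 0.000486), at 4.11 ± 0.87 with siRNA a and 4.69 ± 0.41 with siRNA b. In the other direction, A_24_P383478 was 5.03-fold lower (log2 -2.33, SE 0.05, adjusted p = 2.02e-05), at -2.21 ± 0.12 and -2.45 ± 0.12. The probe p28318 was 3.33-fold lower (log2 -1.74, SE 0.24, adjusted p = 0.00595), at -1.58 ± 1.02 with siRNA a, where it did not pass alone (adjusted p = 0.0570), and at -1.89 ± 0.42 with siRNA b. On slide 1 alone, with 4 arrays, A_23_P64828 (log2 4.52, adjusted p = 0.0535) and p28318 (log2 -1.76, adjusted p = 0.0848) did not pass, at log2 ratios near those of all 6 arrays.

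**Figure D1:**
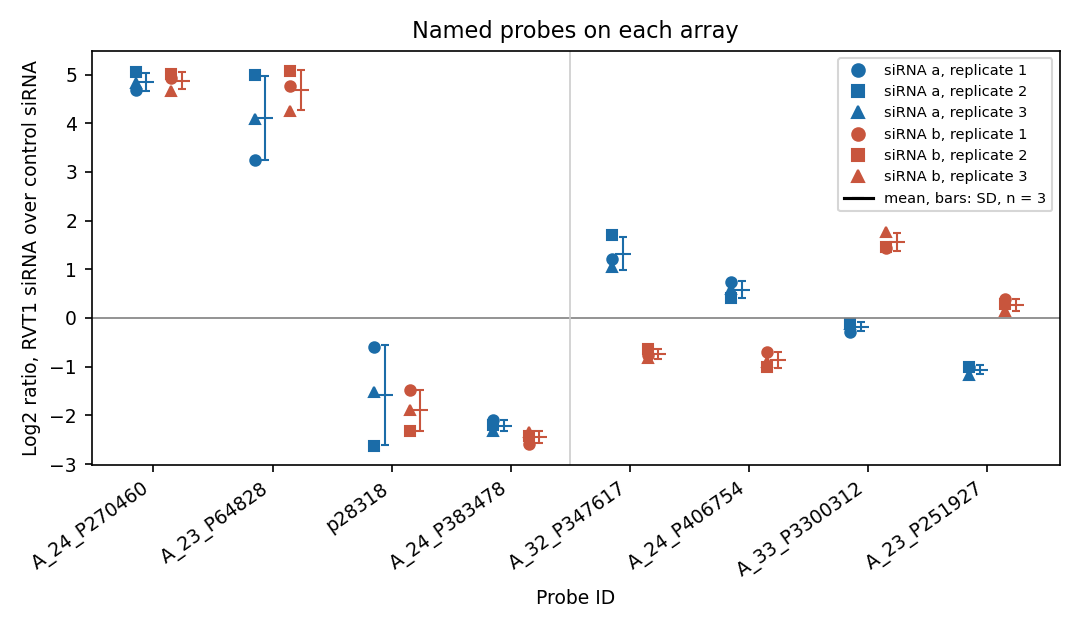
Log2 ratio of RVT1 siRNA over control siRNA (vertical axis) for the probes named in the text (horizontal axis), on each of the 6 arrays, with the mean and SD of the 3 arrays per siRNA. A_24_P270460 and A_23_P64828 lie above 0 and A_24_P383478 and p28318 below 0 on all 6 arrays, while the other 4 probes separate siRNA a from siRNA b.

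In the mean of both siRNAs, 53 of the 85 tRNA probes passed as lower and 1 as higher, and 11 of the 16 numbered RNAs passed as higher and 1 as lower. The tRNA median was -0.40 (camera adjusted p = 9.67e-37; adjusted p = 0.112 with an estimated correlation) and that of the numbered RNAs 0.65; the joint class of small RNAs had a median of 0.35 (camera adjusted p = 0.000333; adjusted p = 0.807 with an estimated correlation). With the replicate number as a block, which can make the error too small here, 70 tRNA probes passed as lower and 12 numbered RNAs as higher. Of the 10 probes whose identifiers name rRNA, 4 passed as higher and none as lower. The class median was 0.08 (camera adjusted p = 0.133, or 0.0150 with the replicate block, and adjusted p = 0.877 with an estimated correlation). The class leaves out the 13 numbered RNAs within the rRNA number range, so it does not show that rRNA as a whole stayed unchanged. Small nucleolar and Cajal body RNAs, which guide chemical changes in other RNAs, showed no class shift: their 282 probes had a median of 0.02 (adjusted p = 0.919), with 26 passing as higher and 15 as lower. The 90 probes for small nuclear RNAs, parts of the splicing machinery, had a median of -0.03 (adjusted p = 0.397), with 6 higher and 3 lower. The 4 probes for vault RNAs, parts of a large cytoplasmic ribonucleoprotein particle, had a median of -0.18 (adjusted p = 0.308 by camera) and none passed. Fry, which does not compare a class with other probes, gave adjusted p = 0.000735 for vault RNA in the mean of both siRNAs, 0.00434 for siRNA a and 0.193 for siRNA b. The vault RNAs were separated from the joint class after their ratios had been seen. In the mean of both siRNAs, fry gave adjusted p = 0.0584 for the joint class. Camera with an estimated correlation gave adjusted p = 0.452 for vault RNA.

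Of the classes that the identifiers call RNS and imsncRNA, left undefined in the files, RNS had a median of -0.046 over 1106 probes, with 49 higher and 116 lower (camera adjusted p = 0.00402; adjusted p = 0.750 with an estimated correlation). The imsncRNA median was -0.020 over 736 probes, with 46 higher and 82 lower (adjusted p = 0.0590). For siRNA a the medians were -0.033 and -0.0078 (adjusted p = 0.0618 and 0.221). For siRNA b they were -0.055 and -0.036 (adjusted p = 0.00274 and 0.0346, or 0.0174 and 0.0562 with the replicate block, and 0.664 for both with an estimated correlation). Both siRNA b calls rested on replicate 1, the only array whose log2 ratios followed the GC content of the probes (r = -0.211, against -0.0164 to 0.0149 on the other 5). Without it the medians were -0.018 and -0.00015 (adjusted p = 0.571 and 0.625), and with the GC trend removed per array -0.021 and -0.0098 (adjusted p = 0.434 and 0.471). The imsncRNA call was also lost without siRNA a replicate 1 (adjusted p = 0.0528) and with the slide as a block (adjusted p = 0.0792). The mean of both siRNAs includes that array, and its class tests were not run without it. With median centring the RNS medians were 0.13 for siRNA a and 0.14 for siRNA b and the imsncRNA medians 0.12 and 0.12, beside 0.12 and 0.14 for all probes.

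**Figure D2:**
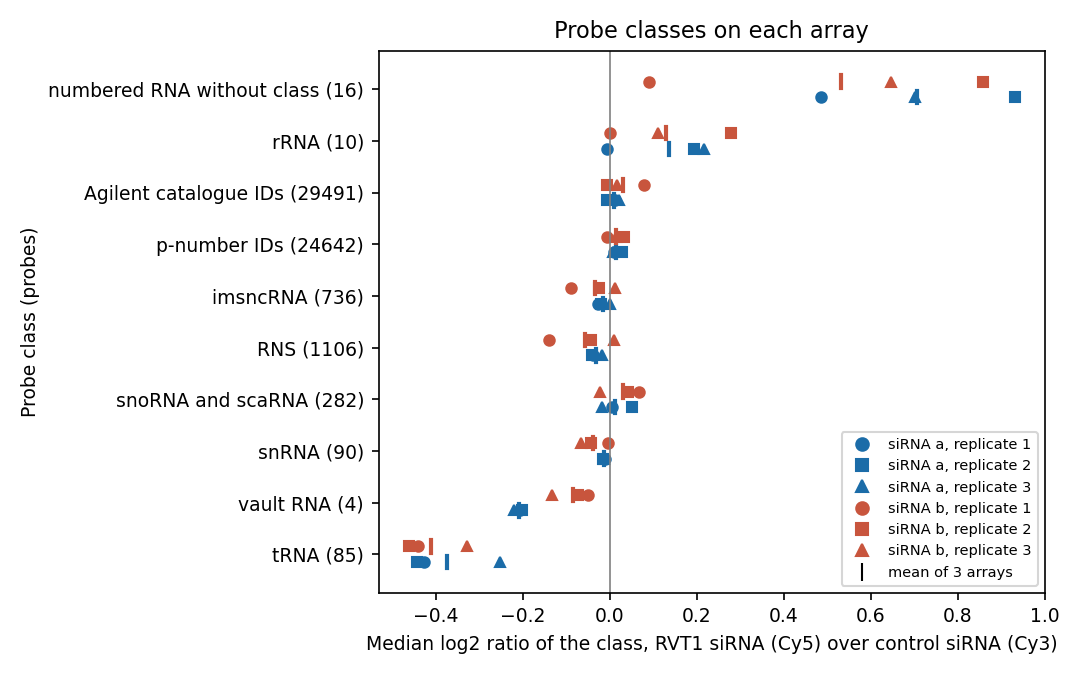
Median log2 ratio of RVT1 siRNA over control siRNA (horizontal axis) for each probe class (vertical axis, with its number of probes), on each of the 6 arrays, with the mean of the 3 arrays per siRNA. The tRNA medians lie between -0.46 and -0.25 and the numbered RNA medians between 0.09 and 0.93; without loess the tRNA medians over arrays were -0.01 and -0.03.

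In all, 11763 of 56463 probes passed in the mean of both siRNAs, 6939 higher and 4824 lower, and of the 104 with at least a 4-fold change 103 were higher. With the replicate number as a block 17313 passed, a count that leaves the spread between replicate numbers out of the error. The share of higher probes, 59.0%, became 77.8% of 26656 probes with median centring (20749 higher, 5907 lower) and 73.9% of 12707 with the processed signals (9392 higher, 3315 lower). It fell to 53.5% of 11699 with the authors' table and 53.7% of 12235 without siRNA b replicate 1. With the slide as a block 8171 probes passed, with the header's slide as the block 5848 passed, and 21 passed on slide 1 alone. The count was 5631 or 5542 without siRNA a replicate 2 or 3, and 6101 or 6922 without siRNA b replicate 2 or 3.

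The log2 ratios had the same sign with both siRNAs for 71.4% of all probes, for 90.9% of those that passed for siRNA a and for 87.5% of those that passed for siRNA b. The mean log2 ratios of siRNA a and siRNA b had Pearson's r = 0.665 and Spearman's rho = 0.570 across 56463 probes, which are not independent replicates. Of the probes that passed as higher, 832 did so for both siRNAs, against 98.6 for independent lists of 1318 and 4223. Of those that passed as lower, 394 did so for both, against 32.8 for lists of 715 and 2594, and 29 passed in opposite directions. Independent lists are not a no-change value here. Both tests shared 1 estimate of the spread per probe, and the arrays were paired by replicate number, so some overlap is built in. On slide 1 alone r was 0.656 and on slide 2 alone 0.591. Over the 6 pairs of arrays with different siRNAs and different replicate numbers r averaged 0.433, from 0.270 to 0.559, against 0.562 over the 3 pairs of the same number. No array pair had the dyes exchanged, so a dye effect alike on all arrays would be part of each comparison with the control and of this correlation.

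**Figure D3:**
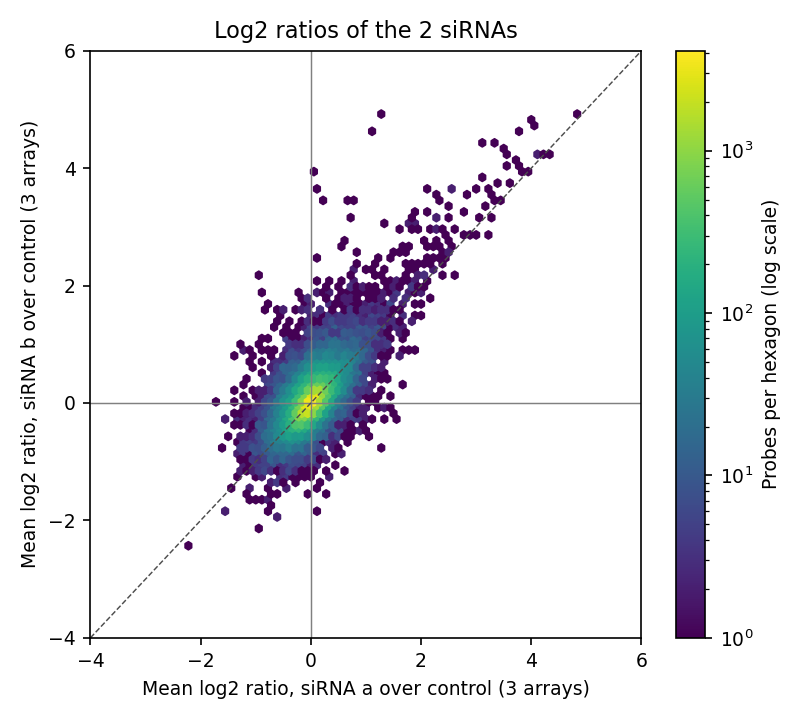
Mean log2 ratio of siRNA b over its control (vertical axis) against that of siRNA a over its control (horizontal axis), 3 arrays each, for the 56463 probes with both values; colour gives the number of probes per hexagon on a log scale. The cloud runs along the diagonal, with Pearson's r = 0.665.

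The last comparison asked which log2 ratios differed between siRNA a and siRNA b. Each siRNA had its own control siRNA, so a difference between the 2 controls would be part of this comparison. Among the probes with the smallest p and no overlap between the groups, A_32_P347617 had a log2 ratio of 1.32 ± 0.34 with siRNA a and -0.74 ± 0.10 with siRNA b (SD, n = 3 each), and A_24_P406754 had 0.58 ± 0.17 and -0.87 ± 0.16. The other way, A_33_P3300312 had -0.18 ± 0.10 with siRNA a and 1.56 ± 0.19 with siRNA b, and A_23_P251927 had -1.06 ± 0.09 and 0.27 ± 0.13. None of these 4 passed: the adjusted p of the difference was 0.0610 for each, and 0.0442 with the replicate number as a block, within a range of 0.0442 to 0.910 over the alternatives. The size of the difference depended on the processing for A_32_P347617, at 2.06, or 3.73 with the processed signals and 3.74 with the authors' table, and for A_33_P3300312, at -1.73, or -2.97 and -2.96. A_24_P406754 moved too, at 1.45, or 2.12 and 2.13, while A_23_P251927 was at -1.33, or -1.35 and -1.34. A_32_P347617 and A_33_P3300312 lay well above background on only 2 of 3 arrays in at least 1 channel, and A_24_P406754 on all 3 in both. In limma 0 of 56463 probes passed, while 6055 had an unadjusted p under 0.05, against 2823 by chance. With the replicate number as a block 9218 had an unadjusted p under 0.05 and 18 passed, 5 higher and 13 lower with siRNA a than with siRNA b, and without siRNA b replicate 1 the unblocked count was 2. The groups did not overlap for 15.9% of the probes, against 10% if the 6 arrays were exchangeable; that share and the 2823 leave out the pairing by replicate number. The tRNA probes differed by 0.07 in median log2 ratio between the siRNAs (adjusted p = 0.188) and the joint class of small RNAs by 0.14 (adjusted p = 0.248, or 0.180 with the replicate block).

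Control spots on the arrays covered 2 enzymes of glycolysis, GAPDH and PGK1, with 10 spots per probe, and were not part of the tests. The GAPDH probe with suffix 3 had a log2 ratio of -0.22 ± 0.22 with siRNA a and -0.23 ± 0.09 with siRNA b (SD, n = 3 each), below 0 on all 6 arrays, but 0.32 and 0.41 with median centring in place of loess. The GAPDH probe with suffix 5 was at -0.06 ± 0.20 and 0.03 ± 0.11, or 0.47 and 0.66 with median centring and -0.15 and -0.0066 with the processed signals. The PGK1 probe with suffix 3 was at -0.19 ± 0.39 and -0.10 ± 0.30, or 0.27 and 0.44 with median centring, and that with suffix 5 at 0.04 ± 0.41 and 0.01 ± 0.11, or 0.38 and 0.42 with median centring.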

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

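The comparison of siRNA a with siRNA b and its replicate block were planned before the data were examined; the spike-in value was picked out after it was seen.

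The log2 ratios of siRNA a and siRNA b, each over its own control siRNA, differed at 18 probes when the replicate number was a block. This was by a test of the difference itself, against 0 without the block. A difference between the controls cannot be told apart from one between the siRNAs. Of these, 5 had a higher and 13 a lower log2 ratio with siRNA a, by 1.23 to 2.08 in size with a median of 1.58, and 17 showed no overlap between the groups. Without the block the real count was 0, so all 10 splits of the 6 arrays gave as many whatever the data, and the splits test nothing there; the highest other count was 0. With the block, 1 of the 4 splits that part all 3 pairs gave as many, with 0 as the highest other against 18, and 4 splits are too few for a share under 0.05. The splits with the block part as many pairs as the real one and differ from it by exchanging siRNA a and siRNA b within 1 replicate number.

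The E1A spike-in spots, controls outside the comparisons, had a median log2 ratio of 1.68 on the array of siRNA b replicate 3, against -0.26 to 0.36 on the other 5 arrays.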

How the results depend on the processing

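Of the alternatives below, the slide from the file headers, the GC trend, slide 1 alone, the pairs of arrays, the correlation on each slide and without each array, and every alternative for probe classes and named probes were chosen after the results were seen. The tRNA and numbered RNA medians, the correlation and the named probes did not reverse under any alternative run, and of the other classes only RNS and imsncRNA were run through all of them. In order for siRNA a and siRNA b, the RNS medians turned to 0.13 and 0.14 and the imsncRNA medians to 0.12 and 0.12 with median centring, beside 0.12 and 0.14 for all probes. With the processed signals RNS turned to 0.018 for siRNA a, and imsncRNA to 0.047 and 0.00079; for siRNA a imsncRNA also turned to 0.0043 with the header's slide as a block and 0.0047 with the GC trend removed. The GAPDH and PGK1 control probes with suffix 3, and for siRNA a the GAPDH probe with suffix 5, changed sign with median centring, and for siRNA b the GAPDH probe with suffix 5 did so with the processed signals (0.03 to -0.0066). In order for siRNA a, siRNA b and both against the control, the counts of probes were 10868, 17399 and 26656 with median centring, 4, 3762 and 5848 with the header's slide as a block, 2, 2 and 21 on slide 1 alone (4 arrays), and 333, 856 and 510 with a fold of at least 2 as well. For siRNA a and siRNA b they were 6903 and 11906 with the replicate block and 464 and 3702 with only the 3 arrays of that siRNA; for siRNA a alone, 4254 with scaling between arrays and 780 with the slide as a block. Leaving out 1 array gave 12 to 3360, 1196 to 6098, and 5542 to 12235. Between siRNA a and siRNA b, 18 probes passed with the replicate block, 1 with an intensity trend, 12 with the GC trend removed, and 0 to 2 without 1 array. The cause was not tested, except that where named fewer arrays were fitted, a fold was added, or the replicate block took spread out of the error. The remaining alternatives gave counts within 1.5 times the main one.

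The numbered RNA medians stayed above 0, from 0.45 (the authors' table) to 1.34 for siRNA a and 0.39 to 1.26 for siRNA b, both highest with median centring. The tRNA medians stayed below 0, from -0.42 to -0.01 for siRNA a and -0.51 to -0.03 for siRNA b, both ends nearest 0 from median centring. With an estimated correlation between probes the medians, unchanged at -0.37 and -0.41, no longer passed (adjusted p = 0.114 and 0.131), nor did the numbered RNAs at 0.75 and 0.54 (adjusted p = 0.493 and 0.664). For siRNA b the numbered RNAs also failed at 0.39 with the authors' table (adjusted p = 0.0547), 0.44 on slide 1 alone (0.0659) and 0.54 with fry (0.220), and ranged from 0.44 to 0.77 without 1 array, failing without siRNA b replicate 2 (0.45) or 3 (0.44). Over pairs of single arrays the correlation of the siRNAs averaged 0.433 with different replicate numbers and 0.562 with the same one, while the means of 3 arrays gave 0.665. Gene lists, the targeted transcript and the alternatives that need several probes per gene were not run, for want of gene names, and the 1-colour comparison was not needed. Signal over background limits the rest: 39002 probes lay well above background in both channels on all 6 arrays.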

Other observations

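All tests given here, on tRNA, the numbered RNAs and the correlation, the sign patterns by pairs, and the comparisons of identifiers and sequences, were chosen after the results were seen.

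Probes whose identifiers are consecutive p-numbers tended to move together. Without any 12 shared bases, 17530 such pairs had log2 ratios in the mean of both siRNAs that correlated at 0.175, against 0.102 at a distance of 2 numbers, 0.0706 at 3, 0.0210 at 10 and 0.0320 at 50. Among 14 pairs of probes that were reverse complements of each other, which read opposite strands, the log2 ratios correlated at r = 0.976 (Spearman's rho 0.780), and at 0.625 without the pair farthest from 0, so that r rested largely on that pair. Single probes stand for a ribozyme and for the RNA of the signal recognition particle, which directs proteins to the endoplasmic reticulum. The ribozyme probe had a log2 ratio of 0.28 ± 0.18 with siRNA a and 0.24 ± 0.23 with siRNA b, and the other -0.01 ± 0.08 and 0.24 ± 0.09 (SD, n = 3 each).

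The tRNA probes lay lower in the knockdown channel with both siRNAs. Base composition and brightness of the probes are argued against as the cause: 10000 random sets of other probes, matched to 84 of the 85 on both, had a median log2 ratio of 0.051, and 0 sets were as low as the -0.39 of the tRNA probes. That count overstates the precision, because the tRNA probes were correlated with each other (estimated correlation 0.110). No sets with 1 probe per shared sequence were run for them. The loess step moved the tRNA median, but is argued against as the source of the difference from like probes: with median centring the matched sets had a median of 0.39, the lowest 0.24, against -0.03 for the tRNA probes. A dye effect alike on all arrays, lower tRNA levels after loss of RVT1 and another response to the RVT1 siRNAs cannot be told apart. No dyes were exchanged, and RVT1 itself was not read. The test of a difference between the siRNAs gave an adjusted p of 0.188, and each of these explanations may leave no difference.

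The numbered RNAs lay higher with both siRNAs. Brightness stays open: random sets of other probes of the same brightness were as high in 3 of 10000 cases for the 16 numbered RNAs, a group formed after its ratios had been seen, and in 90 for the joint class, but with 1 probe per shared sequence in 572 for the joint class (median 0.19, matched 0.066) and 1107 for the numbered RNAs. A dye effect stays open here too, as does an effect of the knockdown or another response to the RVT1 siRNAs. The test of a difference between the siRNAs gave an adjusted p of 0.188, or 0.0230 with the replicate block, and 0.671 with an estimated correlation. As 9 of the 16 share 20 bases with another, they may count as fewer than 16 separate RNAs. The identifiers of 13 lie between the lowest and the highest rRNA number. The rRNA identifiers carry a count that rises in step with the RNA number. It runs from rRNA_0 at RNA143561 over rRNA_38 at RNA143599 to rRNA_317 at RNA143878. The 13 thus hold numbers inside that series and may be rRNA. Of the 6 rRNA probes at a log2 brightness of at least 15, 3 passed as higher (0.81 to 0.98) while the other 3 lay between -0.13 and 0.01. The classes were kept as the identifiers name them.

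The log ratios of siRNA a and siRNA b were correlated across probes. A batch shared by arrays of 1 replicate number is argued against as the whole cause by the pairs with different numbers, the lowest of which correlated at 0.270. Base composition is argued against by a correlation of 0.666 once its trend had been removed from each array. A part from such a batch stays open: pairs of the same number averaged 0.562, against 0.433 for different numbers. Control channels of the same number correlated at 0.984 to 0.991, against 0.939 to 0.974 for the same control siRNA. Pairs sharing neither correlated at 0.938 to 0.976, with a mean of 0.954, as for the same control siRNA. Of the 4 sign patterns that turn both arrays of a replicate number together, 1 gave as many as the 11763 probes changed by both siRNAs, with 0 as the highest other count, and 4 patterns are too few for a share under 0.05. A dye effect and a response to RVT1 siRNAs as such cannot be told apart, because the dyes were never exchanged. Arrays of the same siRNA correlated better than those of different siRNAs by 0.180 over pairs with different numbers, with -0.03 as the highest other value and an exact one-sided permutation p of 0.25, the smallest that 4 permutations can give; a difference between the siRNAs could add to a shared dye effect.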
